A study of Mus musculus with 2 samples.

How the data were processed

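Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against H3K9me3, the trimethylated lysine 9 of histone H3 that marks heterochromatin, was done on midbrain tissue of mouse embryos at embryonic day 14.5. Per the labels, both samples came from healthy embryos of both sexes, pooled, of strain B6NTac;B6NCrl/Lap. Replicate 1 pooled the midbrains of 24 embryos and replicate 2 those of 34 embryos, so the replicates were separate tissue pools. Replicate 1 had 2 technical replicates and replicate 2 had 3, and the library size range was 300 to 500 bp. Both samples formed 1 group, so the comparison between samples was replicate 1 against replicate 2, and no group was compared with another.

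The authors' deposited files analysed here were 4 peak lists in narrowPeak format, 1 for each replicate, a pooled list and a list of replicated peaks. Per the deposited README texts, the build was mm10. The same texts state that the pooled list was made from the alignments of both replicates with 2 control files, that the list of replicate 1 used its own alignments with 2 control files, and that the list of replicate 2 used its own alignments with 1 control file. The list of replicated peaks was derived from the pooled list and both replicate lists. The peak caller, the aligner and the rule for replicated peaks were not given in the sources used here. Reads, alignments, signal tracks and control libraries were not analysed here, so the depth per sample is unknown. Peak lists cannot show a region below the caller's threshold, and a difference in the number of reads or of control reads between replicates would move the number of peaks.

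Each deposited peak carried a score for display, a fold enrichment, a −log10 p, a −log10 q and the position of its summit. The fold is the authors' ratio of the peak over the control, and was used to describe, rank or filter peaks within a list. The authors' −log10 p and −log10 q were used likewise. The authors' score and summit entered no result. These units followed from the column order of the format and from the values.

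Peaks on chromosomes 1 to 19, X and Y entered the comparisons, and peaks on other sequences of the assembly were counted apart. Regions prone to artefact signal were not removed from the lists here. Gene positions came from GENCODE release M21 on GRCm38, the build that mm10 names. The representative transcript of a gene was the one with the longest coding sequence, and its first and last exon gave the transcription start site (TSS) and the 3′ exon. Peaks were merged before covered bases were counted. Covered bases were divided among promoter (TSS ± 1 kb), exon, intron and intergenic sequence of protein-coding genes, in that order of precedence. Repeat content was measured as the soft-masked share of the genome sequence. Peaks within 5 kb were joined into domains. Coordinates are given 1-based.

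Tests used rotation. All peaks of a list were moved along each chromosome by a random distance, with wrap-around and without the first 3 Mb of each chromosome but Y, which keeps widths and spacing. The overlap of replicates was tested one-sided and the annotation shares two-sided with 1000 rotations, the gene lists and the zinc finger 3′ exon two-sided with 10000, and the sequence content two-sided with 100. The smallest p these permutation tests can give is 0.001 one-sided and 0.002 two-sided with 1000 rotations, 0.0002 two-sided with 10000 and 0.0198 two-sided with 100. Replicate overlap shares have Wilson 95% confidence intervals, which cover counting error only. Gene lists, 19 in number, were written from gene symbols before the data were examined, as were the tests and the alternatives unless stated otherwise. A list member counted when a peak overlapped its gene body by at least 1 bp, and p-values were adjusted by Benjamini-Hochberg over the 19 lists. In these lists 1 symbol had no match in the annotation. The p-values compare peak positions with rotated positions within these samples, not conditions. The alternative with length-matched genes instead draws single genes at random. It does not keep the clustering of gene families, so its p-values can be too small. With rotated peaks, 2.11% of 760 simulated gene list tests on 21911 genes had p below 0.05. A list of 200 genes with 20 planted peaks was called in 18 of 20 simulated runs, and lists with 40 or 80 planted peaks in 20 of 20. The planted genes were drawn at random across the genome, and the call used an unadjusted p below 0.05. These runs therefore do not measure the power for clustered families, smaller lists or adjusted p-values.

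Genes and regions were named by a rule fixed beforehand. It took the 10 protein-coding genes with the most covered bases and the 10 of at least 2 kb with the largest covered share, where each replicate also had a peak. From each gene list it took up to 4 members with the most covered bases, or every member with a peak in a list with 5 or fewer. It also took the 5 replicated peaks of highest fold, the 5 domains with the most covered bases, and the 5 peaks of highest fold of each replicate that the other lacked. Other genes are named as chosen afterwards. Alternatives were the pooled list, each replicate alone, a −log10 q of at least 5, other overlap and TSS windows, other gene sets, length-matched genes and other domain gaps. Replicated peaks overlapped by a peak of each replicate were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.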

Results

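H3K9me3 was mapped in the midbrain of mouse embryos at embryonic day 14.5 in 2 biological replicates of a single group, each a pool of embryos. The peak list of replicate 1 held 41078 peaks and that of replicate 2 held 22454, a mean of 31766 ± 13169 (SD, n = 2). The authors' pooled list held 44794 peaks and their list of replicated peaks 17587. On chromosomes 1 to 19, X and Y, the peaks covered 13.05 Mb in replicate 1, 6.94 Mb in replicate 2 and 8.86 Mb in the replicated list, which is 0.325% of these chromosomes. Replicated peaks had a median width of 409 bp and a median fold over control of 3.48, as the authors' values give it. The depth of each library is unknown, since only peak lists were analysed.

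The first comparison was between the replicates. Of the replicate 1 peaks, 27.3% (Wilson 95% confidence interval 26.8 to 27.7%, 40798 peaks) were overlapped by a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 50.9% (50.2 to 51.5%, 22202 peaks) were overlapped by a replicate 1 peak. Rotated peaks gave 0.653% and 1.20% (one-sided permutation test, p = 0.001 for both, the smallest that 1000 rotations can give). The bases covered in both replicates made up 18.1% of those covered in either. The lists differed 1.83-fold in number of peaks. With the same number of top peaks by p taken from both, 35.7% of replicate 1 and 38.0% of replicate 2 peaks overlapped. With at least 50% of the peak covered the shares were 18.2% and 39.7%. Peaks of −log10 q of at least 2 gave 17.5% and 52.7%, and peaks with a fold of at least 4 gave 25.8% and 32.7%. Across the 11124 replicate 1 peaks with an overlap, the fold of both replicates had a Pearson correlation of 0.34 and a Spearman correlation of 0.197. For the −log10 p of the same peaks these were 0.665 and 0.235. These correlations are across peaks of 1 tissue, which are not independent replicates, and carry no p-value.

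The strongest peaks that a single replicate had lay both in and outside the gene families described below. In replicate 1 the peak of highest fold without a replicate 2 overlap lay within the Pcdhg cluster at chromosome 18, 37741182 to 37741512, with a fold of 7.69. The next lay in an intron of the zinc finger gene Zfp942 on chromosome 17, 21929657 to 21930028, with a fold of 7.41. Others lay in an intron of Cux2, a homeobox gene of neurons, with a fold of 6.55, and in intergenic sequence near Fer (fold 6.84) and near Iqsec1 (fold 6.55). In replicate 2 the strongest such peak lay in an intron of 2010111I01Rik on chromosome 13, 63127415 to 63127907, with a fold of 7.70. The others were at Zfp273, Il3ra and Anks1b, each with a fold of 6.01, and near Ifi213 with a fold of 6.53.

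All 17587 replicated peaks were found with identical coordinates in the pooled list. A peak of each replicate overlapped 58.95% of the 17384 replicated peaks on the chromosomes by at least 1 bp, and 39.9% when at least 50% of the peak had to be covered in each. A further 6600 were overlapped in a single replicate, 4651 of them in replicate 1 and 1949 in replicate 2, and 536 in neither. The name of the list therefore does not mean that both replicate lists hold each of its peaks. The 10248 peaks with an overlap in both had a median fold of 3.76, against 3.27 for those with an overlap in a single replicate.

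Along the genome, peak coverage was highest on chromosome 7, with 9774 bp per Mb in replicated peaks. This was 3.17 times the value of the median chromosome. Chromosome 17 followed with 7046 bp per Mb, then chromosomes 4 (5319), 18 (5245) and 13 (4839). The X chromosome had 614 bp per Mb and the Y chromosome 62.2, the lowest values. Chromosomes 7 and 17 ranked first and second, and X and Y last, in each replicate. At −log10 q of at least 5 the order changed, with chromosome 18 (2704 bp per Mb) above chromosomes 7 (2641) and 17 (2339). Peak coverage counts called sequence and does not measure the amount of the mark. Coverage on X and Y was not corrected for the mixed sex of the pools. Chromosome 7 had 12405 bp per Mb in replicate 1 and 7165 in replicate 2, and replicate 1 was higher on each other chromosome too.

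**Figure D1:**
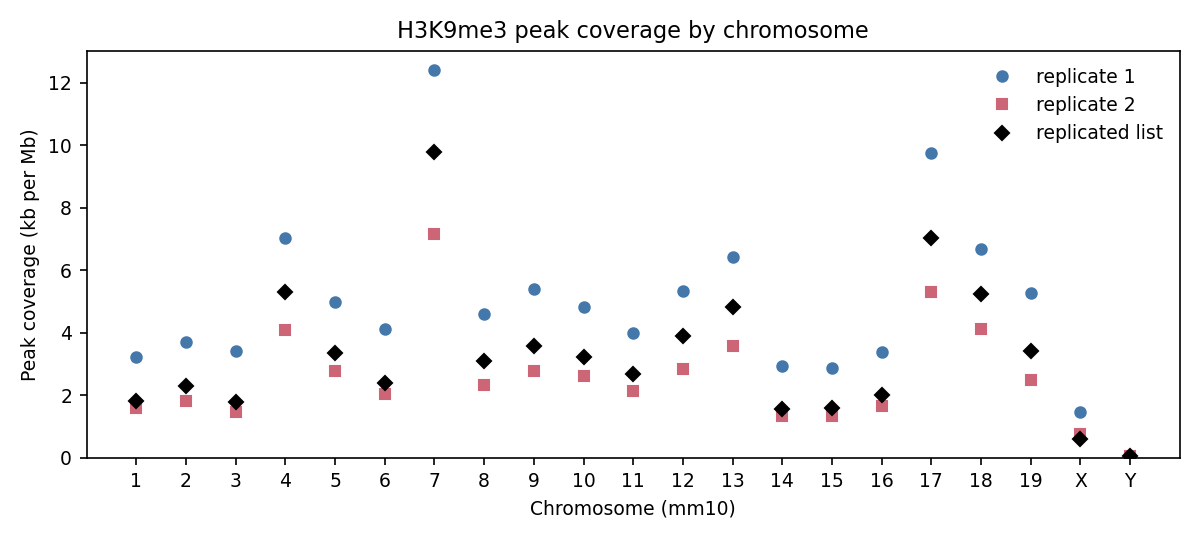
Bases covered by H3K9me3 peaks per chromosome, in kb per Mb of chromosome, for replicate 1 (circles), replicate 2 (squares) and the authors' replicated list (diamonds). Chromosome 7 lies highest and Y lowest in each of the 3 lists, and replicate 1 lies above replicate 2 on each chromosome.

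Relative to genes, replicated peaks were enriched in exons and promoters and depleted in introns. Exons of protein-coding genes held 7.38% of the covered bases against 3.59% with rotated peaks, and promoters 2.79% against 1.78%. Introns held 28.1% against 36.4% (two-sided permutation test, p = 0.002 for each of these 3, the smallest that 1000 rotations can give). Intergenic sequence held 61.8% against 58.2% (permutation p = 0.122). With the pooled list, and with replicate 1 alone, the intergenic share was 64.2% and passed the test (permutation p = 0.002 for both), and with peaks of −log10 q of at least 5 it was 51.8%, below the rotated 58.6% (permutation p = 0.0639), where the intron share no longer passed (30.4%, permutation p = 0.0759).

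Peak sequences held fewer masked repeats than rotated positions. The soft-masked share was 24.7% against 33.9%, and the GC content 43.7% against 42.1% (two-sided permutation test, p = 0.0198 for both, the smallest that 100 rotations can give). The observed over expected CpG ratio was 0.173 against 0.193 (permutation p = 0.0198). In peaks of −log10 q of at least 5 the CpG ratio lay on the other side, at 0.215 against 0.192 (permutation p = 0.0198).

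Of 21911 protein-coding genes, 2434 held a replicated peak, against 4368 with a replicate 1 peak and 2905 with a replicate 2 peak. Of the 19 gene lists, 6 held peaks in more members than rotated peaks gave, namely the clustered protocadherins, germline DMR genes, imprinted genes, zinc finger genes, vomeronasal receptors and immune receptor families. No list passed the test for fewer members, with or without adjustment. Of the 62 genes named by the rule fixed beforehand, replicate 1 covered more bases than replicate 2 in 58, and the replicates differed by at least 1.5-fold in 22, so the covered bases given below, which refer to the replicated list unless stated, depend on the replicate.

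**Figure D2:**
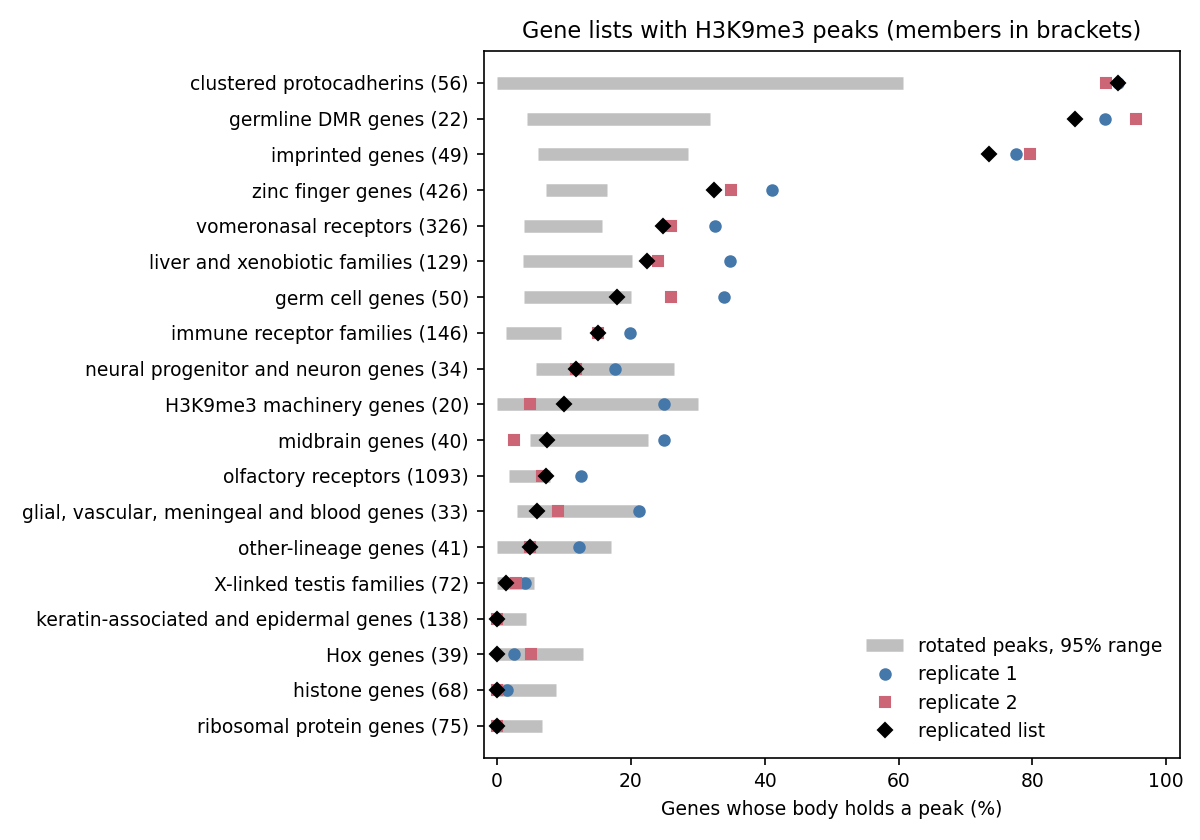
Share of the members of each gene list whose gene body holds a peak, in percent, for replicate 1 (circles), replicate 2 (squares) and the replicated list (diamonds). Grey bars span the central 95% of the shares that 10000 rotations of the replicated list gave, so they refer to the diamonds, and the number of members stands in brackets. Protocadherins lie at 92.9% and Hox, histone, ribosomal protein and keratin-associated genes at 0 in the replicated list.

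The clustered protocadherins, cell-surface adhesion proteins that give neurons individual identities, had the largest share of members with a peak among the 19 lists in the replicated list and in replicate 1. Germline DMR genes had a larger share in replicate 2 (95.5% against 91.1%) and in the pooled list (95.5% against 94.6%). Of 56 members, 52 (92.9%) held a replicated peak, against 12.9 with rotated peaks (two-sided permutation test, adjusted p = 0.00076). Replicate 1 alone gave 52 members and replicate 2 alone 51. A peak lay at the TSS of 49 of the 52. By subfamily, 12 of 13 Pcdha, 22 of 22 Pcdhb and 18 of 21 Pcdhg genes held a peak, and 11, 20 and 18 held it at the TSS. Gene bodies of Pcdha and of Pcdhg are nested, so a peak can count for several of them. The 4 genes without a peak were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5. They are C-type members at the 3′ ends of their clusters, though not all C-type members, and are named here after their values were seen.

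Within the Pcdhg cluster, Pcdhga1 (chromosome 18, 37661793 to 37841873) had 98752 bp or 54.8% of its gene body in replicated peaks, 93073 bp in replicate 1 and 85290 bp in replicate 2. Pcdhga2, Pcdhga3 and Pcdhgb1 had 95425, 90498 and 85376 bp. Pcdhga4, Pcdhgb2 and Pcdhga5, also among the 10 genes with the most covered bases, had 81166, 76589 and 72665 bp. These gene bodies share their constant exons and are nested, so the same peaks were counted for several of them. The read-through loci Gm42416, Gm37013 and Gm37388, which span the Pcdha to Pcdhg clusters, had 265450, 256496 and 253422 bp for the same reason. Pcdhb21, a single gene of 4705 bp at chromosome 18, 37513621 to 37518325, was covered over 76.7% of its body.

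**Figure D3:**
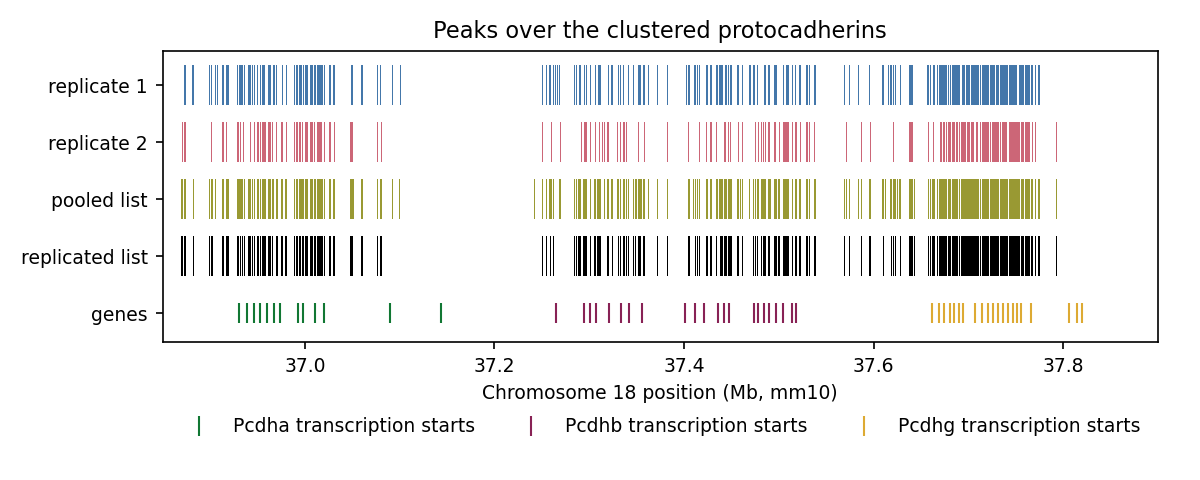
Peaks over the Pcdha, Pcdhb and Pcdhg clusters on chromosome 18 (mm10) from 36.85 to 37.9 Mb, drawn to scale as bars in 4 rows for replicate 1, replicate 2, the pooled list and the replicated list. Ticks in the lowest row mark the transcription starts of the annotated Pcdha, Pcdhb and Pcdhg genes, and the densest block of peaks is the domain at 37653139 to 37777813 in the Pcdhg cluster.

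Zinc finger genes, which encode DNA-binding proteins, many of them transcriptional repressors, held peaks in 138 of 426 members (32.4%), against 47.5 with rotated peaks (adjusted permutation p = 0.00076, two-sided permutation test). Replicate 1 gave 175 members and replicate 2 gave 149. Zfp943 on chromosome 17 had 18202 bp covered, Zfp981 on chromosome 4 had 16333 bp, Zfp606 on chromosome 7 had 14373 bp and Zfp873 on chromosome 10 had 13951 bp. The last 2 were covered over 80.1% and 83.9% of the gene body, and Zfp110 on chromosome 7 over 87.5%.

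The peaks of zinc finger genes lay at the 3′ end. The last exon held a replicated peak in 104 genes (24.4%) and the TSS window in 7 (1.64%). The difference of 97 genes compares with 1.98 for rotated peaks (95% range −5 to 10, two-sided permutation test, p = 0.0002, the smallest that 10000 rotations can give), and it was 107 in replicate 1 and 103 in replicate 2. Among the other 21485 protein-coding genes, 363 held a peak in the last exon and 333 at the TSS, a difference of 30 against −50.9 with rotated peaks (permutation p = 0.002). Genes with another member within 100 kb held a peak in the last exon in 76 of 244 cases, and those without in 28 of 182. When the list was counted at the TSS ± 1 kb, 7 members held a peak against 8.82 with rotated peaks (adjusted permutation p = 1). At the TSS ± 5 kb there were 47 against 25.4 (adjusted permutation p = 0.094), so the call of the zinc finger list rests on gene bodies.

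**Figure D4:**
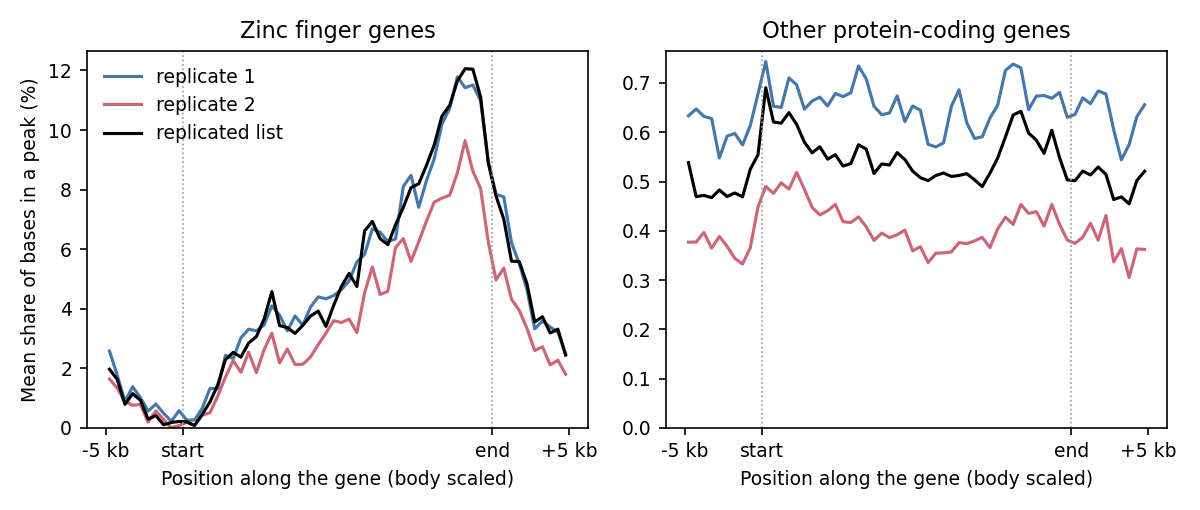
Mean share of bases in a peak, in percent, along zinc finger genes (left) and other protein-coding genes of at least 1 kb (right), with the gene body scaled to equal length and 5 kb on either side, for both replicates and the replicated list. The vertical axes differ in scale: the zinc finger profile of the replicated list reaches 12.1% between 90 and 92% of the gene body, and that of other genes stays at or below 0.69%.

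Imprinted genes, which are expressed from a single parental allele, held peaks in 36 of 49 members (73.5%), against 8.11 with rotated peaks. Genes at germline differentially methylated regions (DMRs) held peaks in 19 of 22 members (86.4%), against 3.402 (adjusted permutation p = 0.00076 for both, two-sided permutation test). The 22 are all part of the imprinted list, and of its other 27 genes 17 held a peak. Gnas, which encodes the stimulatory G protein alpha subunit, had 7644 bp in replicated peaks, 5768 bp in replicate 1 and 4637 bp in replicate 2. Trappc9 had 6017 bp (5287 bp in replicate 1 and 3825 bp in replicate 2), the potassium channel gene Kcnq1 5687 bp (8011 and 3045 bp) and the signalling adaptor gene Grb10 5565 bp (6505 and 5103 bp). The antisense RNA gene Kcnq1ot1, which lies within Kcnq1, had 4687 bp (5341 and 2672 bp) and a peak at its TSS, and Mest had 4682 bp with a peak at its TSS. The germline DMR genes without a peak were H19, Mcts2 and Rasgrf1, named after their values were seen.

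Among chemosensory receptors, the vomeronasal receptors held peaks in 81 of 326 members, against 28.2 with rotated peaks (adjusted permutation p = 0.00076). These were 38 of 206 Vmn1r and 43 of 120 Vmn2r genes. Vmn2r60 on chromosome 7 had 10177 bp covered, Vmn2r16 on chromosome 5 had 8174 bp, and Vmn2r61 and Vmn1r73, both on chromosome 7, had 7490 and 6632 bp. Replicate 2 covered fewer bases of these 4 genes, with 6767, 5694, 3616 and 2875 bp. Olfactory receptors held peaks in 80 of 1093 members against 42.8 with rotated peaks, which did not pass (adjusted permutation p = 0.195). They passed in 1 alternative, against length-matched random genes (39.8 members, adjusted permutation p = 0.000475). That alternative ignores the clustering of the family, so its p-value can be too small. The receptors with a peak included Olfr139 with 4321 bp, Olfr77 with 2735 bp, Olfr398 with 2373 bp and Olfr365 with 2209 bp, of which replicate 2 covered 1666, 1790, 1482 and 1250 bp. At −log10 q of at least 5, Olfr139, Olfr398 and Olfr365 had no peak.

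Immune receptor families held peaks in 22 of 146 members against 6.71 with rotated peaks (adjusted permutation p = 0.00697, two-sided permutation test). Of these, 9 were Skint genes, a family that includes the epidermal T cell selecting gene Skint1, and 7 were Klra genes of natural killer cells. The list is wider than its name, since it also takes in defensin and interferon genes. Peaks lay in 4 of 42 Defb, 0 of 22 Defa and 0 of 13 Ifna genes. Skint6 had 34702 bp covered, Skint5 31379 bp, Skint2 12480 bp and Skint10 10483 bp, all on chromosome 4. Replicate 1 covered 46350, 46559, 12216 and 12402 bp of them and replicate 2 covered 23361, 24780, 8841 and 6022 bp. At the TSS ± 1 kb the list had 9 members against 1.94 and did not pass (adjusted permutation p = 0.0678). In liver and xenobiotic families, 29 of 129 members held a peak against 13.7 (adjusted permutation p = 0.0516, not passed). The list passed with replicate 1 alone (45 members, adjusted permutation p = 0.0483), with peaks of −log10 q of at least 5 (23 members, adjusted permutation p = 0.00095), with at least 500 bp of the gene covered (27 members, adjusted permutation p = 0.00543), with peaks overlapped in both replicates, chosen after the data were seen (28 members, adjusted permutation p = 0.00814) and against length-matched random genes (adjusted permutation p = 0.000475). It did not pass with replicate 2 alone (31 members against 16.7, adjusted permutation p = 0.0817), with the pooled list (41 members, adjusted permutation p = 0.117) or at the TSS ± 1 kb and ± 5 kb (adjusted permutation p = 0.653 and 0.494). The 29 were 11 of 47 Cyp genes, 9 of 21 Sult genes and all 9 Ugt1a genes, whose products conjugate bilirubin and drugs. The Ugt1a genes share 3′ exons, and Ugt1a7c, Ugt1a10, Ugt1a8 and Ugt1a6b had 10989, 9991, 9991 and 9990 bp from overlapping peaks. The test against length-matched genes treats such genes as separate draws, so its p-value for this list can be too small. Ugt1a1 (chromosome 1, 88211959 to 88218997) was covered over 94.3% of its body, and 0 of 22 Mup and 0 of 20 Serpina genes held a peak.

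Germ cell genes held peaks in 9 of 50 members against 5.72 with rotated peaks (adjusted permutation p = 0.438). At the TSS ± 1 kb there were 7 members against 0.655 (adjusted permutation p = 0.00127, two-sided permutation test), and at the TSS ± 5 kb 7 against 2.16 (adjusted permutation p = 0.0431). Gene bodies also passed with the peaks overlapped in both replicates, an alternative added after the data were seen (9 members against 3.54, adjusted permutation p = 0.0337), but not with replicate 1 alone (adjusted permutation p = 0.28), replicate 2 alone (adjusted permutation p = 0.0929) or the pooled list (adjusted permutation p = 0.231). The germ cell genes with the most covered bases were Taf7l on the X chromosome with 1008 bp, Ddx4 with 828 bp, Meioc with 755 bp and Stag3 with 583 bp, each with a peak at its TSS. Replicate 1 covered 297, 610, 1001 and 387 bp of these genes and replicate 2 covered 486, 810, 257 and 269 bp. Of the X-linked testis families, Rhox13 alone among 72 members held a peak, of 551 bp.

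Lists of neural and other cell types did not pass the test with the replicated list. Midbrain genes held peaks in 3 of 40 members against 5.15 (adjusted permutation p = 0.63), namely Corin with 855 bp, Lmx1a, a regulator of dopaminergic progenitors, with 383 bp, and Aldh1a1 with 206 bp. With replicate 2 alone the list was lower, with 1 member against 6.32 (adjusted permutation p = 0.0244), but with replicate 1 alone it had 10 members against 10.4 (adjusted permutation p = 1). Neural progenitor and neuron genes held peaks in 4 of 34 members against 5.73 (adjusted permutation p = 0.743), namely Syt1 (1399 bp), Myt1l (1079 bp), Snap25 (628 bp) and Ncam1 (579 bp). Glial, vascular, meningeal and blood genes held peaks in 2 of 33 against 3.52 (adjusted permutation p = 0.792), Pdgfrb and Tek. Other-lineage genes held peaks in 2 of 41 against 3.05 (adjusted permutation p = 0.998), Zfp42 and Trp63. H3K9me3 machinery genes held peaks in 2 of 20 against 2.44 (adjusted permutation p = 1), Atf7ip with 3783 bp and Hells with 240 bp. Replicate 2 had no peak in Lmx1a, Aldh1a1, Ncam1, Zfp42 or Hells.

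No replicated peak lay in any of 39 Hox, 75 ribosomal protein, 68 histone or 138 keratin-associated and epidermal genes. Rotated peaks gave 1.14, 2.14, 0.91 and 2.11 members, so these counts of 0 did not pass the test (adjusted permutation p = 1, 0.438, 1 and 0.593). With the pooled list, the ribosomal protein genes were lower, with 0 members against 4.50 (adjusted permutation p = 0.0413), and 9 Hox genes held a peak against 2.82 (adjusted permutation p = 0.0718), which did not pass.

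Replicated peaks within 5 kb formed 9756 domains, of which 554 held 5 or more peaks and 132 spanned at least 20 kb. These counts were 1084 and 240 with replicate 1 alone, 649 and 128 with replicate 2 alone and 1251 and 309 with the pooled list. With peaks joined within 1 kb they were 265 and 4, and within 10 kb 515 and 305. Peaks of −log10 q of at least 5 gave 76 and 23. The domain with the most covered bases was that of the Pcdhg cluster, chromosome 18, 37653139 to 37777813, with 63 peaks and 101598 bp. The next lay over the 3′ end of the Ugt1a locus and Mroh2a on chromosome 1, 88211401 to 88258078, with 44212 bp in 10 peaks. A Pcdha domain at chromosome 18, 36898906 to 36981272, had 42494 bp and a Pcdhb domain at 37469595 to 37539231 had 37331 bp. A domain over Zfp369 and the predicted gene Gm10775 on chromosome 13, 65242591 to 65297780, had 37428 bp.

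The peak of highest fold, 15.1, was intergenic on chromosome 7, 12010274 to 12011267, with the vomeronasal receptor gene Vmn1r77 25484 bp away as the nearest protein-coding gene. Klf14, a transcription factor gene on chromosome 6, held the next at 30956280 to 30959453 with a fold of 14.97, in an exon, and 95.9% of its body was covered. A peak of fold 10.9 on chromosome 4, 146480311 to 146481116, lay in an exon of Gm26573 or Gm13245, loci not annotated as protein-coding, and the predicted gene Gm21887 on the X chromosome held peaks of fold 10.9 and 10.8. Further genes covered over most of their body were Gm21738 (100%), Scgb2b24 (94.2%), Mroh2a (86.8%) and Asmt (76.2%), the gene of the last enzyme of melatonin synthesis. Scgb2b24 had 1838 bp covered in replicate 1 and 298 bp in replicate 2.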

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

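The tests of replicate 2 peaks near replicate 1 peaks and of the fold at equal p were chosen after the results were seen.

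Signal lay outside the chromosomes analysed. On 21 other sequences of the assembly, 203 replicated peaks covered 212 kb, with 280 such peaks in replicate 1 and 252 in replicate 2. Their median fold was 3.76, against 3.48 for all replicated peaks.

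Many peaks were found in a single replicate, 29674 of replicate 1 (72.7%) and 10908 of replicate 2 (49.1%). Chance calls alone are argued against, since 150 zinc finger genes held a replicate 1-only peak and 97 a replicate 2-only peak, above the 95% rotation ranges of 65 to 108 and 27 to 62. Domains split at different places were predicted to put most of these peaks within 5 kb of a peak of the other replicate. For replicate 1 the share was 38.9%, short of that prediction, and for replicate 2 it was 55.3%. Rotated peaks gave 6.45% and 11.2%, so both shares lay above rotation. Replicate 2 has fewer peaks to lie near, which lowers the share of replicate 1, so split domains remain open for both. Calls near the detection threshold remain open, since the 4079 replicate 1 peaks of lowest p were overlapped 4.03 times as often as the 4079 of highest p (62.5% against 15.5%). More reads behind replicate 1 also remain open. At −log10 p of 4 to 5 its median fold was 3.13 against 3.42, a difference of −0.283, which is the direction that deeper data would give. Replicate 1 was called with 2 control files and replicate 2 with 1, and an effect of the controls on the fold was not separated from depth. No biological explanation was tested.

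Replicated peaks held little soft-masked sequence, 24.7% against 33.9% with rotated peaks. Exons, which hold few repeats, are not the whole cause, since the 15150 peaks that touch no exon were still at 26.8%, below the rotation range (32.5 to 35.6%). A loss of reads that align to many copies cannot be told apart from a true lack of the mark, because the 1 kb flanks held 32.9%, within the rotation range of 32.7 to 35.4%. No biological explanation was tested, and the reads that would settle it were not analysed here.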

How the results depend on the processing

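No paired analysis was possible because the labels give 1 group. Peaks overlapped in both replicates and zinc finger genes in clusters were alternatives chosen after the data were seen. Of 85 alternative values of the main results, 73 kept their direction and their side of the threshold or stayed within the spread. The cause of the other changes was not tested. For covered length the spread was the SD of the replicates, 4.32 Mb, which grows as they disagree. So 13.05 Mb in replicate 1 and 6.94 Mb in replicate 2 both counted as unchanged from 8.86 Mb. The replicate overlap, the exon and promoter enrichment, the soft-masked and GC shares and the zinc finger 3′ exon kept their direction and side of the threshold in each alternative. The size of the replicate overlap varied, from 17.5 to 35.7% of replicate 1 peaks and from 32.7 to 52.7% of replicate 2 peaks. Left out 1 replicate at a time, the intergenic share was 62.1 to 64.2% and the number of domains 12648 to 22916. The pooled list gave an intergenic share of 64.2%, 15.7 Mb covered, 22379 domains and 4362 protein-coding genes with a peak, and peaks overlapped in both replicates gave 6124 domains. A −log10 q of at least 5 gave an intergenic share of 51.8%, an intron share of 30.4%, a CpG ratio of 0.215, 2.65 Mb covered, 2218 domains and 772 protein-coding genes with a peak; with fewer peaks, length and counts fall by construction. Replicated peaks overlapped in both replicates were 58.95% at 1 bp against 39.9% at 50%.

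Of 171 alternative values of single gene lists, 145 kept theirs, 11 newly passed, 2 no longer passed and 13 changed direction, and 5 to 8 of the 19 lists were higher in each alternative. For zinc finger genes the TSS ± 1 kb gave 7 members, below rotation. The other changes of direction were in lists that did not pass either way. Machinery genes had 1 member at −log10 q of at least 5 and 2 at the TSS ± 5 kb. Hox genes had 9 with the pooled list and 2 without replicate 1. X-linked testis families had 1 at the TSS ± 1 kb, 2 at the TSS ± 5 kb and 1 at 500 bp covered. Glial, vascular, meningeal and blood genes had 2 at −log10 q of at least 5 and 2 at 500 bp covered, midbrain genes 4 at the TSS ± 5 kb, neural genes 4 at 500 bp covered and olfactory receptors 10 at −log10 q of at least 5. Of 62 named genes, 5 had no peak in replicate 2 and 16 none at −log10 q of at least 5. Covered bases of named genes moved by at least the SD of the replicates in 140 of 310 alternative values. The same held for 50 of 105 values of coverage per chromosome and 17 of 50 values of named regions. The number of protein-coding genes with a peak moved by more than 1.5-fold in 3 of 5 alternatives. Unknown depth limits what the absence of a peak shows.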

Other observations

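The scan of symbol families, the peaks of lowest p, the comparison with other V segment arrays, the measure of recurring 25-mers and the correlation with zinc finger gene density were chosen after results were seen.

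The array of immunoglobulin heavy chain V segments, which B cells join to build antibodies, held H3K9me3 peaks in the embryonic midbrain. In the Ighv array on chromosome 12, 113572927 to 116010093, 436 replicated peaks covered 9.03% of the sequence (9.77% in replicate 1, 5.93% in replicate 2), and 46 of 183 segments held a peak, against 1.22 with rotated peaks. Rotation ran along the whole chromosome. It therefore does not show whether the segments were favoured over the sequence between them. The array was picked from a scan of 288 families of at least 10 symbols with 50000 rotations, in which 4 were called, Zfp, Ighv, Vmn and Pcdhb, and Ighv belonged to no list above (45 of 181 symbols with a peak, two-sided permutation test, adjusted p = 0.0115 over the 288 families). Klra (7 of 11 members) and Nlrp (9 of 17) did not pass (adjusted permutation p = 0.33 and 0.346).

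Identical stretches of tandem copies lay under few of the peak bases. In the array, 11.1% of these bases were covered by a 25-mer that recurs in it, and 14.3% in the peaks that touch a segment. Peaks shifted within the array gave a 95% range of 42.0 to 72.2%. For most peak bases this argues against reads shared between identical stretches of the array. How reads that align to several copies were handled is unknown, and dropping them would also lower these shares. Copies outside the array or missing from the reference were not measured, so reads from those remain open. Segments without a peak were covered by recurring 25-mers over a mean of 80.3% of their bases, against 32.1% for those with a peak. A loss of reads that align to several copies could therefore hide further peaks. In Igkv, Trav and Trbv, 1 of 160, 1 of 128 and 0 of 35 segments held a peak, within their rotation ranges. Calls of a single replicate are argued against by 51 segments in replicate 1 and 39 in replicate 2, above the upper ends of the rotation ranges of 11 and 7. A difference between the strain and the reference in this array was not tested and stays open, as does a biological cause, since the design holds a single group.

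At the imprinting control region of H19 (chromosome 7, 142580248 to 142582833) no replicated peak was found, while the pooled list covered 630 bp, replicate 1 231 bp and replicate 2 none. The 10 replicated peaks of lowest p had a median fold of 3.57, near the list median of 3.48. Of these, 5 lay at Sfi1 and Drg1 on chromosome 11 and 2 at Gm26917 and CT010467.1 on chromosome 17, such as chromosome 11, 3197452 to 3200118, with a fold of 3.78. A low p at such a fold does not show strong enrichment. Whether these peaks reflect the mark or an artefact of the region was not tested, since reads and controls were not analysed.

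A hypothesis was that chromosomes with more zinc finger genes have a higher H3K9me3 peak coverage. Across 20 chromosomes (Y left out), replicated coverage per Mb and zinc finger genes per Mb had a Pearson correlation of 0.871 (permutation p = 3e-05) and a Spearman correlation of 0.648 (permutation p = 0.00242, adjusted p = 0.00488 over 5 correlations). Both replicates gave similar Spearman values, 0.639 and 0.638. Without chromosomes 7 and 17, which lie farthest from the median density, the values were 0.559 (permutation p = 0.0162) and 0.517 (permutation p = 0.0313). Coverage includes the peaks at those genes, so the correlation could restate their enrichment. Without sequence within 100 kb of a listed zinc finger gene the Spearman correlation was 0.592 (permutation p = 0.00657). Peaks within that distance of the listed genes are therefore not the whole of it. Any zinc finger genes outside the list were not taken out, so the test cannot exclude peaks at those. Chromosomes differ in other ways that were not separated.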
